A study of Arabidopsis thaliana with 4 samples.

How the data were processed

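The samples were whole seedlings of Arabidopsis thaliana, kept 2 days in the cold and then grown for 14 days, per the labels. RNA was labelled with biotin, 1 colour, and hybridised to Affymetrix ATH1 arrays, per the labels' protocols. The values are signal intensity on a linear scale, 1 per probe set, made by the authors with MAS5 and GCOS per the submitters' processing notes, with versions and detection calls not given in the sources used here. From the values, each array had the same mean of 100 after trimming 2% at each end, so the deposited intensities are already scaled between arrays. Groups were taken from the sample labels: 2 knockout arrays, 1 enhancer trap and 1 wild type. The labels do not say whether the 2 knockout arrays come from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Spread in MAS5 signals grows at low intensity, which makes folds of dim probe sets uncertain.

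The 64 control probe sets were left out of the tests, leaving 22746. Signals were taken as log2(signal + 1), the pseudocount being the 10th percentile of all signals (1.06) rounded, so log2 changes understate the change of dim genes. Probe sets with a mean log2 value at or above the 40th percentile (4.58) were kept, which left 13648. One model with 3 group means was fitted to the 4 arrays in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with an intensity trend, and two-sided p-values were adjusted by Benjamini-Hochberg at 0.05. It has 1 residual degree of freedom, from the knockout arrays, and 41.8 prior degrees of freedom. Each adjusted p without another name is from this limma fit. A probe set passes, rises or falls where this adjusted p is under 0.05. The lone arrays are assumed to vary as the knockout arrays do.

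A gene whose lower side lay at or under the highest signal of the 27 Bacillus control probe sets on any array (10.6) has only a bound there, the mean signal of the brighter side over 10.6, given as "at least". The named genes followed a rule fixed before the data were examined. They are CES and its list, the 8 largest rises and 8 largest falls past the test against wild type (changed the same way in both knockout arrays, where these are compared), and the 4 largest each way between the mutant lines. Up to 4 members per gene list are also named. In the knockout fewer than 8 genes fell past the test, and no gene qualified by size to fill the places. Genes in the chromosome 4 stretch other than by this rule, psbA, and those under the filter were chosen after their values were seen.

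Gene names come from the platform annotation, in which 13513 probe sets not used as controls have 1 gene, 503 have several and 8730 are not listed. Of the 13513, 13436 matched the gene table of assembly TAIR10.1, which gave names and gene order. Only probe sets with 1 gene are named, and a gene with several is represented by the one with the highest mean. Of the tested probe sets, 6086 are not listed, which leaves many members of the gene lists unnamed.

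The 20 gene lists were fixed before the data were examined: CESTA and related genes, sterol and brassinosteroid biosynthesis, brassinosteroid inactivation, signalling and growth genes, gibberellin, early auxin, cold, photosynthesis, clock, salicylic acid, jasmonate, rapid stress, heat shock, flavonoid, glucosinolate, iron and phosphate, root, flowering, and reference genes. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, adjusted within each comparison. The version with an estimated correlation rests on the 1 residual degree of freedom and can hardly pass. Its values neither uphold nor overturn a call. A further 14 families defined by gene symbol, and the plastid genes, were added later and adjusted over 15 lists; the plastid list was added after 1 of its calls had been seen. Shared changes were compared with 100 simulations of unchanged groups that share the wild-type array; for the overlap of calls, lists of the observed lengths were taken by p in each direction, a test added after the overlap was seen. The gene-order scan used 10000 permutations of the calls, with the stretch of 100 genes chosen after the pattern had been seen in a table of chromosome bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

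On simulated data of 13648 genes with 200 changed, the fit recovered 71.0% of log2 changes of 1 for knockout against wild type, 65.5% for enhancer trap against wild type and 75.0% for knockout against enhancer trap. For log2 changes of 2 it recovered 99.5%, 98.0% and 99.5%. Between 1 and 11 unchanged genes were called in these runs. Each simulated gene had normal noise at the spread fitted for its intensity, alike on all arrays. The recovered shares thus hold only where the lone arrays vary as the model assumes. Alternatives covered the pseudocount, quantile normalization and median centring, the filter, the trend, each knockout array left out, fits of the compared arrays only, and an estimated correlation. A pseudocount of 16 and a fit with knockout and wild type as 1 group of 3 were added after the data were seen. Pairing was not possible, since wild type and enhancer trap have 1 array each. Coordinates of the TAIR10.1 gene table served only to order the genes and are not reported here.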

Results

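Transcript levels were measured in whole Arabidopsis thaliana seedlings, 14 days old and grown under 16 h of light and 8 h of dark at 24 °C, with 1 single-colour ATH1 array per RNA sample. The labels give 2 arrays of a T-DNA line named as a knockout of CESTA (CES), 1 array of a line named as a CESTA enhancer trap, and 1 array of the Columbia-0 wild type, all with the same listed genetic background. CES encodes a basic helix-loop-helix transcription factor of the brassinosteroid response. Each array held 22810 probe sets, and the median signal lay between 38.5 (knockout replicate 1) and 39.6 (wild type). Wild type and enhancer trap had no replicate, and the number of arrays limits the precision of every value.

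CES itself was read first, as a check of the labels. Its signal was 4124 in the array labelled enhancer trap, where CES ranked as probe set number 45 from the top. In wild type it was 0.533, and in the knockout arrays it was 7.29 and 5.35. The highest signal of any Bacillus control probe set, which has no target in the plant, was 10.6 over the 4 arrays, so the wild-type and knockout readings all lay within background. CES in the array labelled enhancer trap was therefore at least 388-fold above that background level. The labels tag this line as a gene knockout as well as an enhancer trap, and its CES signal goes against the first of these tags. In the knockout line the CES probe set checks nothing, because wild type had no signal above background to lose, and the position of the probes relative to the insertion was not analysed here.

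The comparison of the array labelled enhancer trap with wild type asks which transcripts differ in the line with high CES signal. It sets 1 array against 1, so a trait of the line and a deviation of either single array cannot be told apart. COR15A, which encodes a chloroplast protein that protects membranes during freezing, rose by 3.42 on the log2 scale (SE 0.353, adjusted p = 1.06e-09), from a signal of 18.15 to 204.3. AT5G62360, a pectin methylesterase inhibitor-like gene, rose by 2.92 (SE 0.209), and AT4G33720, of the PR-1-like CAP family, by 2.77 (SE 0.324). AT1G75960, an AMP-binding enzyme gene, rose by 2.63, AT5G57785 by 2.44, AT1G30760, of the berberine bridge enzyme family, by 2.30, and AT4G19430 by 2.14. The signals of these 7 genes in both knockout arrays were all below those in the enhancer-trap array.

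Of the 8 named genes with the largest falls past the test, 6 lay within background in this array. AT4G20480 read 144.7 in wild type and 0.438 in the array labelled enhancer trap, a difference of at least 13.6-fold. AT4G16870 was at least 11.5-fold lower, the TIR-NBS-LRR resistance gene AT4G19500 at least 7.65-fold and the glutaredoxin gene AT4G15660 at least 7.11-fold. AT1G64360 was at least 6.03-fold lower, and AT5G52760, of the heavy-metal-associated domain family, at least 4.25-fold. ZW9, a TRAF-like gene, stayed above background and fell by 4.38 (SE 0.185), from 806.5 to 37.9. QQS, an orphan gene that affects starch content, fell by 3.35 (SE 0.404), from 154.4 to 14.2. The plot of signal by array shows ZW9 and QQS beside CES and members of the cold and auxin lists.

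**Figure D1:**
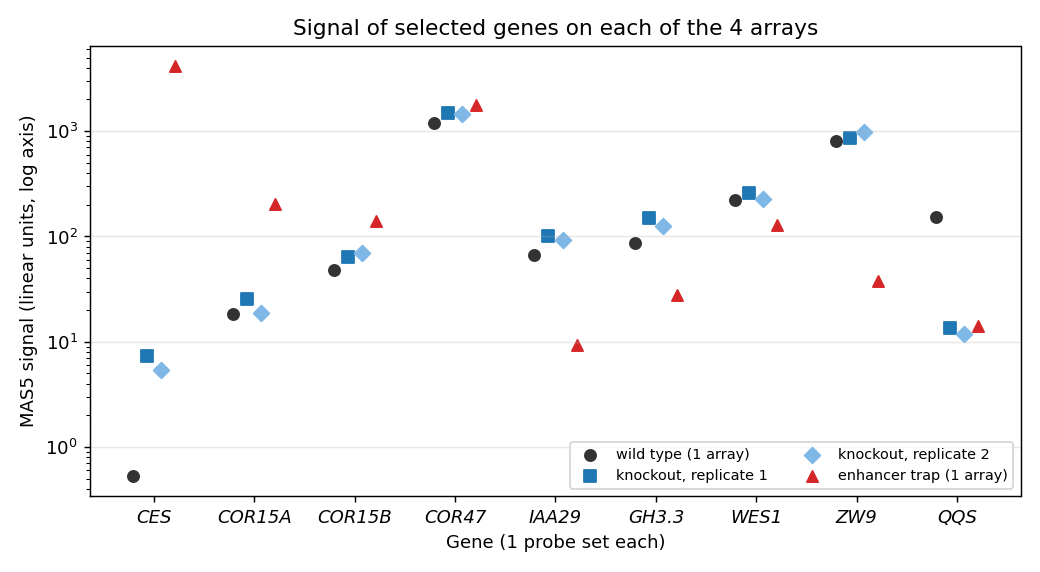
MAS5 signal in linear units on a log axis for CES, COR15A, COR15B, COR47, IAA29, GH3.3, WES1, ZW9 and QQS (1 probe set each), with 1 point per array and no error bars. CES reads 4124 in the array labelled enhancer trap against 0.533 in wild type, and QQS reads 154.4 in wild type against 11.97 to 14.24 in the other arrays.

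In all, 586 of 13648 tested probe sets passed the test in this comparison, 278 higher and 308 lower, and 278 of the 586 carry 1 annotated gene. Larger changes occur among probe sets that the annotation does not list. The largest rise among those was 3.75, from 9.61 to 141.7, above that of COR15A. An unlisted probe set that stayed above background fell by 4.60, from 1355 to 55.1, more than ZW9. By size alone, 400 probe sets differed at least 2-fold, against 83 between the 2 knockout arrays. The spread behind this test comes from the 2 knockout arrays alone, and both lone arrays are assumed to vary as those do. Without the signal filter the count was 153 and without the intensity trend it was 205, with the higher share moving from 47.4% to 27.5% and 30.2%. The GAPDH 3'/5' signal ratio, a sign of RNA integrity, was 1.38 in the array labelled enhancer trap and 1.70 to 2.01 in the others, while the actin ratio was 2.55 against 2.04 to 3.12.

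Of the gene lists fixed beforehand, 4 had at least 3 tested members, with 3 each. The full lists hold 12 early auxin, 13 cold, 26 gibberellin and 7 reference genes, so the list tests speak only for the measured members. All 3 tested members of the early auxin response list fell: IAA29, an auxin-response repressor gene, was at least 6.22-fold lower, GH3.3, an auxin-conjugating enzyme gene, fell by 1.61 (SE 0.263), and WES1 (GH3.5), of the same enzyme family, fell by 0.80 (SE 0.206). Their median change was -1.61 (camera adjusted p = 5.28e-09, and adjusted p = 0.353 with an estimated correlation, which decides nothing on 1 residual degree of freedom). Of the cold response list, COR15A and COR15B rose, the latter by 1.52 (SE 0.270), and COR47 was at 0.57 (adjusted p = 0.0553). The median of the cold list was 1.52 (camera adjusted p = 5.28e-09, and adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, 3 members passed in each of these lists. The gibberellin list, measured through the receptors GID1A, GID1B and GID1C, had a median of 0.27 (camera adjusted p = 0.123) with 0 members past the test over all genes and 1 adjusted over the list alone. The reference genes PEX4 (UBC21), AT4G34270 and AT2G28390 had a median of 0.12 (camera adjusted p = 0.569) with 0 members past the test either way.

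Lists with 1 or 2 tested members had no list test. Of the brassinosteroid-induced growth genes, the expansin gene EXPA8 fell by 1.53 (SE 0.202, adjusted p = 4.58e-07). PDF1.2, a defensin gene and jasmonate marker, fell by 1.77 (adjusted p = 0.000188). DFR, of anthocyanin synthesis, rose by 1.74 (adjusted p = 0.0104). Of the root markers, the root-hair expansin gene EXPA7 rose by 1.32 (adjusted p = 0.00191), while PYK10 was at 0.22. No change passed the test for BIM1 (0.64, adjusted p = 0.117) of brassinosteroid signalling, BAT1 (-0.17) of brassinosteroid inactivation, the light-harvesting genes LHCB4.1 (-0.23) and LHCB4.2 (-0.24), the clock gene GI (-0.06), or WRKY53 (-0.19) and STZ (-0.31) of the rapid stress list. None of these genes passed in the knockout against wild type. Of the 14 sterol and brassinosteroid biosynthesis genes, 0 were named on the array by the annotation used, and 0 members were tested of the salicylic acid, heat shock, glucosinolate, iron and phosphate, and flowering lists.

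The knockout arrays against wild type ask which transcripts differ in the line named as a loss of function. QQS fell by 3.499 (SE 0.350, adjusted p = 1.27e-08), from 154.4 to 13.55 and 11.97. GSTU25, a glutathione transferase gene, rose by 1.41 (SE 0.189, adjusted p = 1.89e-05). AT2G34930, of the leucine-rich repeat family, rose by 1.46 (SE 0.308), the expansin-like gene EXLA1 by 0.89 (SE 0.154), and the nitrate transporter family gene AT3G45710 by 0.88 (SE 0.176). AT5G59170, within background in wild type, was at least 3.33-fold higher in the knockout, while AT5G25240 rose by 0.93 and AT3G59350 by 0.83. Between the knockout and the array labelled enhancer trap, AT5G59170, AT5G25240 and AT3G45710 differed by -0.016, 0.018 and -0.012, so these rises are not particular to the knockout.

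Among the falls in the knockout, AT5G67390 fell by 1.41 (SE 0.305), with signals of 27.8 and 69.4 in its 2 arrays against 118.4. AT4G19430 fell by 1.31 (SE 0.285), opposite to its rise in the array labelled enhancer trap. The plastid gene rpl16, which encodes a ribosomal protein, fell by 1.00 (SE 0.179), and the extensin-like gene AT1G26250 fell by 0.88 (SE 0.180).

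In this comparison 25 probe sets passed the test, 17 higher and 8 lower, and 13 carry 1 annotated gene. Of the 25, 8 also passed the same way in the knockout against the array labelled enhancer trap. CES is among the 17, at background on both sides, so no fold is given for it. Of all tested probe sets, 12 were at least 2-fold away from wild type in both knockout arrays, 7 higher and 5 lower. When knockout replicate 2 was instead tested against a pair of wild type and knockout replicate 1, 26 probe sets passed, and 17 passed for knockout replicate 1 against a pair of wild type and knockout replicate 2, so the count of 25 lies between those of the mixed pairings. Without the signal filter 0 passed by limma, with 1211 of 22746 at an unadjusted p under 0.05 where 1137 are due by chance, and without the intensity trend 2 passed. With quantile normalization 41 passed, and with median centring 59.

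The early auxin list had a median of 0.54 in the knockout (camera adjusted p = 0.00792, and adjusted p = 0.644 with an estimated correlation), with 0 members past the test over all genes and 1 adjusted over the list alone. The cold list had a median of 0.30 (camera adjusted p = 0.0125, and adjusted p = 0.644 with an estimated correlation), with 0 members past the test either way. The gibberellin list (median -0.06, camera adjusted p = 0.585) and the reference genes (median -0.24, camera adjusted p = 0.556) had 0 as well.

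**Figure D2:**
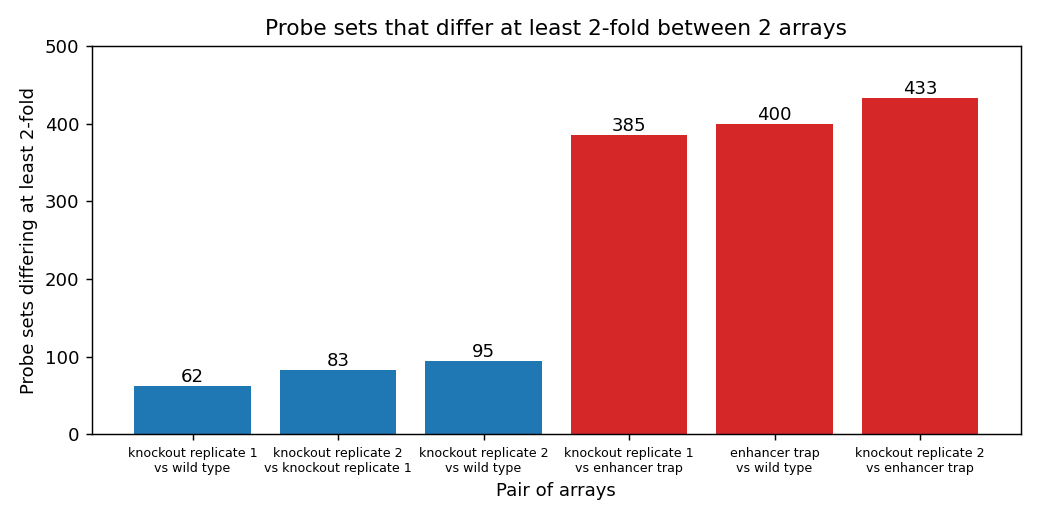
Number of the 13648 tested probe sets that differ at least 2-fold between 2 arrays, with 1 bar per pair of arrays, red where the pair holds the array labelled enhancer trap and blue otherwise. The 3 red bars lie between 385 and 433, and the 3 blue bars between 62 and 95.

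The knockout against the array labelled enhancer trap compares the mutant lines without the wild-type array. AT4G20480 was at least 12.5-fold higher in the knockout, AT4G16870 at least 10.5-fold and AT4G15660 at least 5.36-fold, and ZW9 was higher by 4.56 (SE 0.161, adjusted p = 1.38e-25). CES was at least 388-fold lower in the knockout. AT4G19430 fell by 3.46 (SE 0.285), COR15A fell by 3.16 (SE 0.306) and AT4G33720 fell by 3.03 (SE 0.281). Of the early auxin list IAA29 was at least 9.08-fold higher, GH3.3 was higher by 2.27 (SE 0.228) and WES1 by 0.92 (SE 0.178), with a list median of 2.27 (camera adjusted p = 5.14e-12, and adjusted p = 0.302 with an estimated correlation). Of the cold list COR15A and COR15B were lower, and COR15B fell by 1.04 (SE 0.234), with a list median of -1.04 (camera adjusted p = 4.96e-06, and adjusted p = 0.302 with an estimated correlation).

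GID1B, a gibberellin receptor gene, was the 1 member of its list past the test, at -0.86 (adjusted p = 0.0151), with a list median of -0.31 (camera adjusted p = 0.0515). EXPA8 was higher in the knockout by 0.89, PDF1.2 was higher by 1.57, and DFR was lower, at -1.46. The reference genes had a median of -0.21 (camera adjusted p = 0.264), with 0 members past the test. Adjusted over the list alone, 3 members of the auxin list, 2 of the cold list, 1 of the gibberellin list and 0 reference genes passed. In all 817 probe sets passed, 443 higher in the knockout and 374 lower, and 231 passed without the signal filter and 335 without the intensity trend. The share higher in the knockout moved from 54.2% to 70.6% and 64.2% under those settings.

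Changes of the 2 lines against the same wild-type array were set side by side. Both lines were called higher for 11 probe sets and lower for 3, and 2 were called in opposite directions. Lists of the same lengths were drawn by p from simulated unchanged groups that share the wild-type array. They had 7.64 (range 2 to 12) and 4.02 (range 1 to 7) in common over 100 draws, and both overlaps lie within these ranges. In that simulation neither line changes, whereas 445 of the 586 enhancer-trap calls also passed the same way against the knockout arrays. The simulated overlaps may therefore be too high, and they do not settle how much the shared array gives. Independent lists of these lengths would share 0.346 and 0.181, which leaves out the shared array. QQS, EXLA1, GSTU25, AT5G59170, AT5G25240, AT3G45710 and AT5G67390 were among the genes called the same way in both. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.367, against 0.578 (SD 0.0068) simulated for unchanged groups that share 1 wild-type array. In the data, 400 probe sets differed at least 2-fold between the array labelled enhancer trap and wild type. Changes in 1 line only lower r, so an r under the simulated value is not read as less sharing. The covariance was 0.0407 against a simulated 0.0379 (SD 8e-04 over the draws), a difference of 0.00281. This SD leaves out the uncertainty of the simulated variance and of the lone wild-type array, so no shared change is read from the difference. The wild-type array cannot be split, so part of the overlap of calls, which lies within the simulated range, may come from it.

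Genes that passed in the array labelled enhancer trap were unevenly spread over the genome. On chromosome 4, 74 of 1052 tested genes passed (7.03%), against 2.40% to 4.97% on the other 4 chromosomes. The densest stretch of 100 tested genes in gene order ran from AT4G10300 to AT4G14190, with 17 passing, 4 higher and 13 lower, against 3.82% of genes genome-wide (permutation p = 4e-04 over 10000 draws, a test chosen after the pattern was seen). In it AT4G13050 fell by 1.96 (SE 0.338) and CLE44, a peptide signal gene of the vascular cambium, fell by 1.22 (SE 0.327), while AT4G11190 rose by 1.25 (SE 0.218). In the knockout against wild type 0 genes of this stretch passed by limma, with 6 of the 100 at an unadjusted p under 0.05 where 5 are due by chance. AT4G15660, AT4G16870, AT4G19500 and AT4G20480 lie further along this chromosome.

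**Figure D3:**
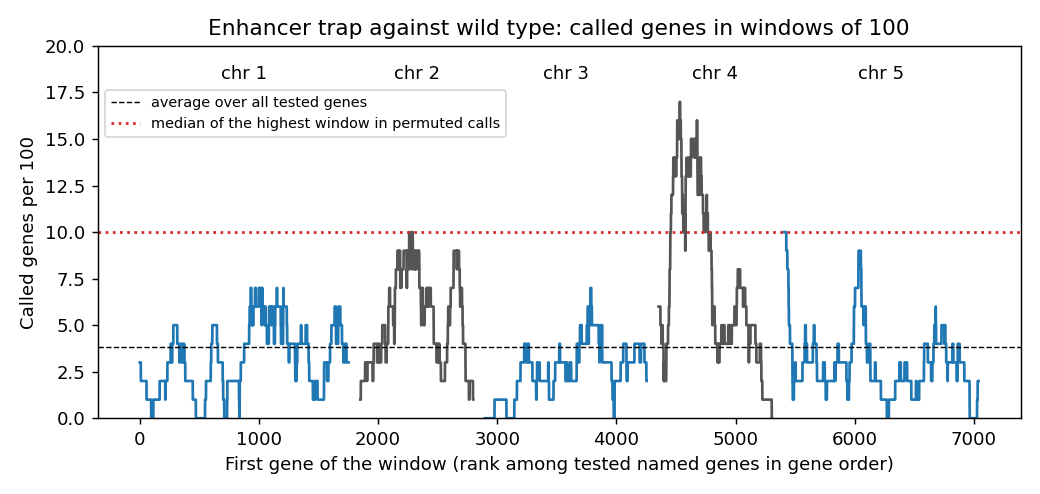
Number of genes past the test, for the array labelled enhancer trap against wild type, in each stretch of 100 tested genes, against the rank of its first gene in gene order over 5 chromosomes; the dashed line is the average of 3.82 and the dotted line the median highest stretch in permuted calls, 10. The highest stretch, on chromosome 4, holds 17.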

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

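The values in this part come from the alternative without the signal filter, planned before the data were examined; the named genes were chosen after their values were seen. Below the signal filter lie 9098 probe sets that the comparisons leave out. When they were included, 10 of them passed the test in the array labelled enhancer trap against wild type, 1 higher and 9 lower, and 18 passed in the knockout against the enhancer trap, 15 higher and 3 lower. Among the 9 were AT4G16880, at 62.0 in wild type and 0.521 in the enhancer-trap array (adjusted p = 0.0159), AT4G08110, AT4G19510, AT2G34840 and the MADS-box gene AGL87, at 43.4 and 0.651 (adjusted p = 0.0216). A filter on the mean of 4 arrays removes genes that are lost in 1 array and dim in the others. No technical or biological explanation was tested for these genes.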

How the results depend on the processing

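The pseudocount of 16 and the fit with knockout and wild type as 1 group of 3 were chosen after the data were seen; the other alternatives were planned. Genes named by the fixed rule, members of the fixed lists and the fixed lists themselves were followed, and none past the test changed sign where it could be tested. The other genes of the symbol families and of the chromosome 4 stretch were not followed, nor were the family lists. At the 60th percentile filter 8 of the 24 followed genes called in the enhancer trap against wild type could be tested. Calls in the enhancer trap against wild type, 47.4% higher as reported, were 50.3% higher with median centring, 50.6% at the 60th percentile filter and 40.6% with 1 group of 3. Knockout against wild type moved from 25 calls to 41 with quantile normalization and 59 with median centring, 0 without the filter and 2 without the intensity trend; the first 2 settings kept all 25. Enhancer trap against wild type moved from 586 to 153 without the filter (143 shared) and 205 without the trend (203 shared), and knockout against enhancer trap from 817 to 231 and 335. The fit with 1 group of 3 gave 534 calls for the enhancer trap, 412 of them shared. The 12 probe sets at 2-fold in the knockout became 7 with a pseudocount of 4, 2 with 16, 1 at the 60th percentile filter and 1176 without a filter. With 1 knockout array left out, which asks for 2-fold in 1 array only, they became 62 to 95. The 400 at 2-fold in the enhancer trap became 3079 without a filter, 202 at the 60th percentile and 223 with a pseudocount of 16. Of 12 list tests 6 passed by camera, and 0 passed at the 60th percentile, where 1 list could be tested. With an estimated correlation 0 passed (0 at an unadjusted p under 0.05, lowest 0.105), an outcome that 1 residual degree of freedom makes nearly certain. The shared correlation of 0.367 became 0.316 at the 60th percentile and 0.301 to 0.334 with 1 knockout array left out, where no degrees of freedom remain for a test. Of the 13 genes called in the knockout, 13 lost the call without the filter and 11 without the trend. Of the 24 followed genes called in the enhancer trap, 5 and 3 did. A pseudocount of 1 equals the reported setting and tests nothing. The cause of these moves was not tested, except where fewer or more probe sets were tested. Signal over background limits the folds of genes near 10.6. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers.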

Other observations

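The symbol families and the tests of the chromosome 4 scan, of a deleted block, of a segment shared with the knockout, of the calls shared with the enhancer trap and of CES background were chosen after the results were seen. In the array labelled enhancer trap against wild type, single members of cell-wall and metabolic families rose. They included the glycosyltransferase genes UGT72B3 (1.42, adjusted p = 0.0349) and UGT71C1 (0.80, adjusted p = 0.0263), 2 of 25 tested. The beta-glucosidase gene BGLU15 rose by 0.95 (1 of 8 tested), the endoglucanase gene GH9C1 by 0.92 (1 of 5) and SCPL34 of the serine carboxypeptidase-like family by 0.93 (1 of 14). GSTU25 rose by 0.72 (1 of 10 glutathione transferases) and the RALF-like peptide gene RALFL22 by 0.69 (1 of 6). Of 9 expansins EXPA7 and EXPB3 (0.65) rose and EXPA8 fell, with a family median of 0.48 (camera adjusted p = 0.132). TBL23 fell by 1.13, the only member called among 14 trichome birefringence-like genes, and psbA, of photosystem II, fell by 0.76, the only call among 66 plastid genes. Of the cytochromes P450, xyloglucan endotransglucosylases, SWEET transporters, AGAMOUS-like genes, calmodulin-like genes and tetraspanins, 0 members passed by limma over all genes. None of the 15 families shifted as a set by camera, with adjusted p from 0.132 to 0.774.

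In the knockout against wild type the 66 plastid genes had a median of -0.18 (camera adjusted p = 3.67e-05) and the 6 xyloglucan endotransglucosylases, which remodel the cell wall, a median of 0.32 (camera adjusted p = 0.0485). With an estimated correlation, which decides nothing on 1 residual degree of freedom, camera gave adjusted p = 0.757 for both. The other 13 families gave adjusted p from 0.0604 to 0.705. Against the same wild-type array the enhancer trap had medians of -0.135 for the plastid genes and 0.34 for the xyloglucan endotransglucosylases. Between the knockout and the enhancer trap these medians were -0.0802 and 0.0598. Both shifts are thus not shown to be particular to the knockout, and a deviation of the lone wild-type array may give them. In the knockout against the enhancer trap 0 of the 15 families passed, with adjusted p from 0.163 to 0.939, and BGLU15, BGLU25 and BGLU44 were lower in the knockout, at -0.88, -0.62 and -0.66.

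Genes changed in the array labelled enhancer trap gathered on chromosome 4. A deletion of the whole stretch would lower nearly all of its 100 genes, and their median was -0.228. That median does not test smaller deletions. It also leaves out AT4G15660, AT4G16870, AT4G19500 and AT4G20480, which lie outside the stretch, so a deletion at those genes was not tested. A segment that the knockout line also carries is argued against by 0 of the 17 called genes moving the same way by 2-fold in both knockout arrays. A segment of another strain may lie there in this line only. The prediction for it, written after the pattern was seen, was a scan p under 0.05 with all called genes of the stretch lower. The scan gave permutation p = 4e-04, but 4 of the 17 rose, so the check cannot tell. Such a segment would not be linked to CES, which lies on chromosome 1. Neighbouring genes that change together would give the scan result too. An effect of CES on this stretch stays open, as untested.

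The 25 calls in the knockout could be chance of single arrays, since 26 probe sets passed when knockout replicate 2 was tested against a pair of wild type and knockout replicate 1, and 17 in the other mixed pairing. A wild-type array that stands apart over all probe sets is argued against by the 7 in which it alone lay 2-fold from the other 3 arrays. The same counts were 20 and 9 for the knockout arrays and 213 for the enhancer trap. These 7 are among the 12 probe sets at least 2-fold from wild type in both knockout arrays. For those 12 changes, wild type is thus often the array that differs, and the check does not speak for them. Within the calls, 14 of 25 were also called the same way in the enhancer trap against the same array. With 1 wild-type array, a deviation of that array and a change that both lines carry cannot be told apart. A loss of CES function stays open.

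CES read higher in the knockout than in wild type. The highest of these signals was 7.29, under the highest control signal of 10.6, so background signal may account for the call. A transcript from the disrupted gene stays open, as untested.

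A hypothesis that the enhancer trap activates genes around CES was tested on the 5 nearest tested genes on each side. Their median change was 0.145, with a range of -0.515 to 0.771, and 1 of the 10 passed the test, AT1G25230 at 0.77 (adjusted p = 0.00503). The 10 genes did not all rise, and their changes went both ways. Because of that spread, the median does not decide for or against activation around CES.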
